A study of Mus musculus with 5 samples.

How the data were processed

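Macrophages at 5 times after LPS were each measured on 1 two-colour cDNA array against whole embryo RNA, so there were 5 samples in 5 groups of 1. The deposited table gives 1 log ratio per probe and array, as the authors processed them. The values were read as log10 ratios of the deposited table. The base is stated neither in the labels nor in the table. It was judged from globin probes, where the median of all 76 at 0 h was -1.54 and 15 read above -1, a size that base 2 would turn into a small difference between blood-rich embryo and macrophage RNA. Scanner, background correction and normalization are not given in the sources used here, and no spot intensities were used, so signal over background is unknown. Per the labels, cDNA was labelled indirectly with amino-allyl chemistry and Cy3; which dye stood in the numerator is not stated. The base, the authors' centring and the direction therefore stay unknown, and the last is given as likely only. The deposited medians of the arrays were 0.04 at 0 h, 0.07 at 0.5 h, 0.05 at 2 h, 0.00 at 7 h and 0.03 at 21 h, and missing values numbered 180, 1104, 232, 257 and 154. The number of arrays limits the precision.

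Of 19828 probes, 14759 had 1 gene symbol in the platform annotation, 170 had several and 4899 had none here. Symbols were updated through the Entrez identifier in a RefSeq table of assembly GRCm38.p6, where 14628 matched. Genes were named from probes with 1 symbol only. Each array was centred on its median over genes with a value on all 5 arrays, the probes of a gene were averaged, and the difference of each time from 0 h was taken for 8452 genes, 2968 of them with at least 2 probes. A gene counted as higher or lower when it differed by 1 or more on the log2 scale, which is 0.301 in log10 units. No test was run, because each group held 1 array. The SD between probes of a gene is given as the only error that these arrays allow; it holds no spread between cultures, labellings or hybridisations.

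Choices were fixed before the data were examined, except where stated. Genes were named by rule: at 0.5 h the 10 largest differences in each direction; at 2, 7 and 21 h the 10 largest in each direction by the smaller of the differences from the 0 h and 0.5 h arrays; members of fixed lists past the size rule, otherwise the 2 highest and 2 lowest; and a panel of 36 inducible genes, of which 15 were measured. Where these were many, the text prints examples, mostly the largest; Postn, Myl1 and the other genes compared with the embryo were chosen after their values were seen. The median of each list with at least 5 measured members was ranked among 10000 random lists of the same size. These were matched on mean log ratio over the 5 arrays in 20 bins, as a description of these arrays. That mean includes the array compared, so the matching is not independent of the difference. B cell, dendritic cell and mast cell markers had fewer measured members and were read gene by gene: Ccr7 differed by 0.11 and Fscn1 by -0.21 at 2 h. Correlations between times were set beside unchanged genes simulated with a shared 0 h array.

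Alternatives set before the data were examined were no centring, quantile normalization, scaling to one median absolute deviation, removal of a loess trend on the mean ratio, other baselines, other ways to join probes, other handling of missing values and other size rules. Alternatives chosen after seeing the data were log base 2 and e, centring on probes, removal of a running median over 400 probe numbers, leaving out the 0.5 h array, leaving out the last stretches of probes, and stretches of 400 probes where the 0.5 h array had a correlation of at least 0.7 with the later arrays, for which list medians and named genes were added last. The first centring computed used the median over probes. It was replaced by the median over genes, the rule fixed beforehand, after counts had been seen, and stands as an alternative. The steps were tested on simulated data for 8452 genes, with normal noise of the pooled SD between probes. At 2 h, 27 of 50 genes raised 2-fold and 50 of 50 raised 4-fold passed the size rule. At 0.5 h, 44 of 50 raised 4-fold and 37 of 50 lowered 4-fold passed, and at 7 h 19 of 50 lowered 2-fold. The differences had heavier tails than this noise at every time, so simulated shares of unchanged genes are no expected values. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, with matplotlib 3.10.9 for figures.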

Results

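The study followed bone marrow-derived macrophages of C3H/HeJ mice, a strain whose Tlr4 carries a mutation that leaves it hyporesponsive to bacterial lipopolysaccharide (LPS). The cells had been differentiated in culture with human CSF-1, the growth factor of the macrophage lineage. They were then exposed to 10 µg per ml LPS of Salmonella minnesota for 0.5, 2, 7 or 21 h, or not exposed (0 h). Each time point was measured on 1 two-colour cDNA array against total RNA from whole C57BL6/J embryos of 17.5 days. There were 5 arrays and no replicates, so no difference between times has a replicate check and none was tested. Of 19828 probes, between 18724 (0.5 h) and 19674 (21 h) had a value, and 8452 named genes had one on all 5 arrays. Differences are in deposited log units, read as base 10. On that reading the fixed size rule of a 2-fold difference is 0.301. The base is not stated, and read as base 2 the same rule would leave 19 genes higher and 7 lower at 2 h.

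By the median of their lists, macrophage genes stood above embryo genes on every array. Over the 0, 2, 7 and 21 h arrays, the centred log ratio averaged 1.22 ± 0.08 (SD over these 4 arrays) for Lyz2, the lysozyme of myeloid cells, and 1.29 ± 0.14 for Lcp1, an actin-bundling protein of leukocytes. The inhibitory receptor gene Lilrb4a averaged 1.61 ± 0.15. The adult beta globin gene Hbb-b1 averaged -1.87 ± 0.15 and Alb, the serum albumin of liver, -1.74 ± 0.19. The median of 12 measured macrophage identity genes lay between 0.53 and 0.70 on the 5 arrays, and that of 24 embryo markers between -0.65 and -0.48. At 0 h, 9 of the 12 and 2 of the 24 were above 0. Cd68 (-0.16 at 0 h) and Tyrobp (-0.05 at 0 h) were below 0 on all 5 arrays. The labels do not say which channel is the numerator. From these medians macrophage over embryo was taken as the direction, and every sign given here rests on it.

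The arrays differed in how well they followed the 0 h array. Across probes, the correlation with 0 h was 0.85 at 2 h, 0.84 at 7 h, 0.75 at 21 h and 0.48 at 0.5 h (Pearson, across probes, which are not replicates). Globin probes marked the 0.5 h array: 55 of them read below -1 on each of the other 4 arrays. At 0.5 h, 28 of these read above -0.5 and 27 stayed below -1. The median of these 55, chosen for low values on the other arrays, was -0.34 at 0.5 h and -1.70 at 0 h; over all 76 globin probes it was -1.54 at 0 h. The SD between probes of the same gene in the difference from 0 h was 0.48 at 0.5 h, 0.16 at 2 h, 0.16 at 7 h and 0.19 at 21 h. For 2968 genes with more than 1 probe, the correlation between a pair of probes of the gene was 0.03 at 0.5 h, 0.14 at 2 h, 0.07 at 7 h and 0.10 at 21 h.

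**Figure D1:**
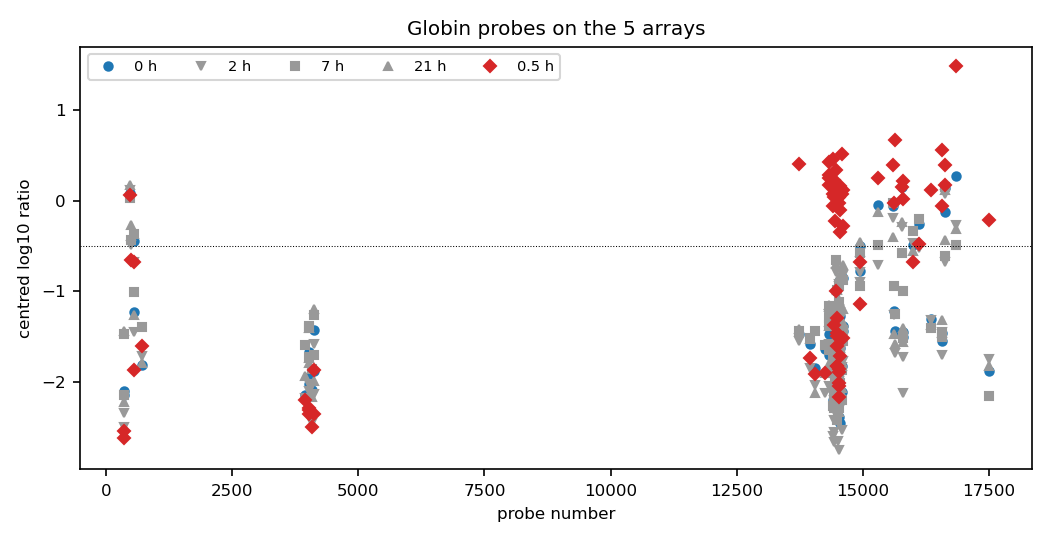
Centred log10 ratio (vertical axis) of each globin probe against its probe number (horizontal axis); symbols stand for the 5 arrays. Of the 55 probes that read below -1 on the other 4 arrays, 28 lay above -0.5 (dotted line) at 0.5 h (red), with numbers from 13728 to 17493. Another 27 stayed below -1, some of them among the same numbers (probe 14518 at -2.04 near probe 14523 at 0.04).

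The 0.5 h comparison asked which genes differed soonest after LPS. Ier2 (1.33) and Egr2 (1.12), transcription regulators of the immediate early class, were higher than at 0 h, each on 1 probe, and Fos was higher by 0.34. Klf2 (-0.45) was lower and Jun differed by -0.22. In the interferon-stimulated list 4 of 22 measured genes were past the size rule upwards, among them Irf7 (1.52 ± 0.87, SD over 2 probes), a transcription factor of the interferon response, and 5 downwards, among them Oasl2 (-1.32) and Gbp2 (-1.06). The globins averaged 0.80 ± 0.97 (Hba-a1, SD over 14 probes) and 0.69 ± 1.15 (Hbb-b1, 20 probes), a spread between probes wider than the mean. Of 24 embryo markers 7 were higher, among them Dcx (1.37) and Afp (0.87 ± 1.20, 2 probes), and 3 lower, Myh3 (-0.58), Col1a1 (-0.43) and Igf2bp1 (-0.39); scaled to one median absolute deviation, Col1a1 was at 0.19.

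Across all genes 1678 were higher and 898 lower at 0.5 h, 30.5% of genes together, where simulated arrays with the probe spread of this comparison put 45.4% of 8252 unchanged genes past the size rule. The simulated noise was normal, while the differences had heavier tails (SD 0.46, and 0.24 when taken from the median absolute deviation). The simulated value is therefore no expected share past the size rule. All probes of a gene were past it upwards in 80 genes and downwards in 36, beside upper limits of 77 and 39.0 (upper end of the central 95% of shuffles of the probes). The largest differences were 3.19 for Septin12, 3.12 for Eya3 and 3.04 for Poll, and -2.46 for Bap1, -2.15 for Dgcr8 and -2.15 for Plk4, each on 1 probe. Of 6 cytokine and chemokine genes 2 were higher, Ccl9 (2.10) and Ccl12 (0.74). Of 7 genes of NF-kB feedback and signalling Nfkbie (1.40) and Birc3 (0.60) were higher and Bcl2a1a lower (-0.34). Among 15 inducible effectors Plaur (1.27) and Arg1 (0.47) were higher and F3 (-0.61), Sod2 and Saa3 lower. The rest of the panel of inducible genes was near 0 or lower: Ptgs2 -0.26, Cxcl10 -0.27, Ccl5 -0.23, Ifit1 -0.43 ± 0.44 (SD over 2 probes), Irf1 -0.23, Sod2 -0.32, Saa3 -0.31, Atf3 -0.14, Marco -0.05, Tlr2 -0.03, Nfkbia -0.04 and Il1rn 0.03. The mean ratio used to match random lists includes the 0.5 h array itself, so percentiles at 0.5 h depend partly on that matching. For the interferon-stimulated list the random range was -0.02 to 0.65, where the median of all genes was -0.01. Of 22 lists with at least 5 measured members, 4 had a median outside the central 95% of random lists matched on mean ratio. These were the interferon-stimulated list (median -0.09, percentile 0.20), lysosome and endocytosis (-0.04, percentile 1.74), ribosomal proteins (0.06, percentile 99.96) and embryo markers (0.04, percentile 99.5). Over the stretches of probes where the 0.5 h array followed the later arrays, 3 of these medians had the other sign: 0.25 for 11 interferon-stimulated genes, -0.0544 for 16 ribosomal protein genes and -0.11 for 12 embryo markers, and Hbb-b1 was at -0.43. With the median probe of each gene the ribosomal median was -0.000415. The share of higher genes among those past the size rule was 65.1%, and 45.5% with the trend on the mean ratio removed (886 higher and 1060 lower), where Egr2 was at -0.23, Fos at -0.36, Irf7 at -0.94, Ccl9 at -1.31, Nfkbie at -0.15 and Plaur at -1.10. That trend is fitted on the mean of the arrays compared. With the wide spread at 0.5 h it can take out differences of genes with high ratios.

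At 2 h, 358 genes were higher and 218 lower than at 0 h. Ptger4, which encodes the prostaglandin E2 receptor EP4, was higher by 1.08 ± 0.16 (SD over 3 probes); among 361 other probes with neighbouring numbers, 19 shared its order of signs over 2, 7 and 21 h, beside 82 of 17675 elsewhere. Irf7 was higher by 0.72 ± 0.45 (SD over 2 probes). Immediate early genes included Egr2 (0.68), Ier2 (0.58) and Junb (0.40), 3 of 13 measured, with no member past the size rule downwards. The list median was 0.12, at percentile 98.0 of random lists. Tlr2, a receptor for bacterial lipoproteins, was higher by 0.36 and Nfkbie, an inhibitor of NF-kB, by 0.56. Egr2, Ier2 and Irf7 were higher still on the 0.5 h array. Steap3, a gene on no fixed list, had the same order: 2.33 ± 0.67 at 0.5 h and 0.63 ± 0.22 at 2 h (SD over 2 probes). Whether position on the array or spot quality gives this order was not tested for these genes.

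Of the 22 interferon-stimulated genes 6 were higher at 2 h, among them Oas1a (0.69), Psmb9 (0.43 ± 0.45, SD over 2 probes) and Gbp2 (0.40), and none lower; the list median of 0.06 lay inside the range of random lists. None of 6 measured cytokine and chemokine genes was past the size rule. Of 12 macrophage identity genes 4 were higher, among them Fcgr1 (0.53) and Fcer1g (0.40), subunits of Fc receptors. With the trend on the mean ratio removed Fcgr1 was at -0.03, and after quantile normalization at -0.21. The 2 h array had a wider range of ratios than the 0 h array (SD across probes 0.42 and 0.33). A wider range by itself would move high ratios up and low ratios down. Of 15 inducible effectors 2 were lower, F3 (-0.39) and the acute phase gene Saa3 (-0.36). Of 24 embryo markers 4 were lower, with Col1a1 at -0.77 and Dcx at -0.45; the list median was -0.14 and the erythroid median -0.13, both inside the range of random lists. Members of other lists past the size rule included Cyc1 (0.37 ± 0.34, SD over 2 probes), Fabp4 (-0.31), H2-Eb1 (-0.37), Cd79b (-0.47) and the mast cell tryptase Tpsb2 (-0.36).

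Ranked by the smaller difference from the 0 h and 0.5 h arrays, the genes highest at 2 h were Zfp169 (1.88), Tbxa2r (1.59), Pigh (1.91), Pcx (1.41) and Ccdc137 (1.89), each on 1 probe, and the lowest were Mybpc1 (-1.01), Prss32 (-0.97) and Klk8 (-0.77). The probes of Tbxa2r, Pigh and Ccdc137 shared the order of signs of Ptger4, higher at 2 and 7 h and lower at 21 h, as did the 1 probe of Gbp2. The fibrinogen gene Fgg was lower by -0.66 on both of its probes. Of the remaining inducible genes, Atf3 differed by 0.30, Il1rn by 0.20, Fos by 0.17, Nfkbia by 0.13, Marco by 0.10, Jun by 0.04, Irf1 by 0.02, Ifit1 by 0.02, Cxcl10 by -0.03, Ccl5 by -0.16, Ptgs2 by -0.16 and Sod2 by -0.20. In 7 genes every one of at least 2 probes was past the size rule upwards and in 8 downwards, beside upper limits of 5 and 6 for shuffled probes. The 7 include Ptger4 and Rbm34, whose probes have neighbouring numbers, and the shuffles did not keep the order of probe numbers. Simulated arrays with the probe spread of this comparison put 4.41% of 8252 unchanged genes past the size rule, where 6.81% were past it in either direction. As at the other times, the simulated noise was normal, so this is no expected share for these arrays. Against the 0.5 h array in place of the 0 h array Irf7 (-0.80), Egr2 (-0.44), Ier2 (-0.75), Nfkbie (-0.84) and Fcer1g (-0.0982) were lower at 2 h and F3 (0.22) and Cd79b (0.0627) higher, and with the 0.5 h array left out of the filter on missing values 539 genes were higher than at 0 h.

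**Figure D2:**
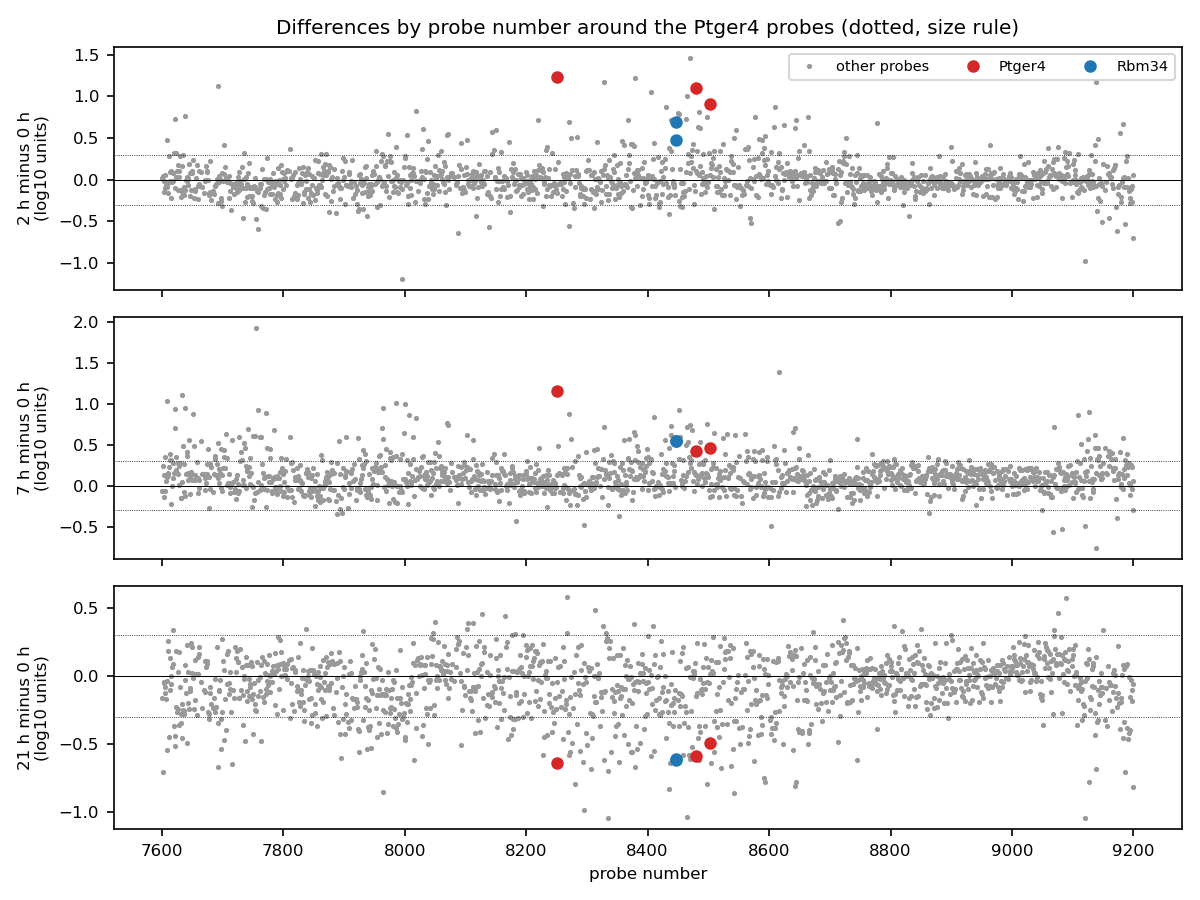
Difference from 0 h (vertical axes, log10 units) of each probe against probe number at 2, 7 and 21 h, with the 3 Ptger4 probes in red, the 2 Rbm34 probes in blue and other probes in grey; each panel has its own scale. Ptger4 averaged 1.08 at 2 h and -0.57 at 21 h, and 19 of 361 neighbouring probes had the same order of signs.

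At 7 h, 283 genes were higher and 118 lower. Ptger4 was higher by 0.68 ± 0.41 (SD over 3 probes) and Nfkbie by 1.12 on 1 probe. Of 22 interferon-stimulated genes 3 were higher, Psmb9 (0.41 ± 0.26, SD over 2 probes), Gbp2 (0.35) and Ifi35 (0.33), and Eif2ak2 was lower (-0.36 ± 0.42, SD over 2 probes). Fcgr1 was higher by 0.52, and at -0.05 after quantile normalization. No immediate early gene was past the size rule, and that list's median of -0.09 lay at percentile 0.81. The 7 measured genes of LPS and TLR recognition had a median of -0.11, at percentile 0.72, with none past the size rule.

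Ccl9 was the 1 cytokine or chemokine gene of 6 past the size rule at 7 h (-0.33). Among inducible effectors Arg1, the arginase of alternatively activated macrophages, was higher (0.32) and Plaur lower (-0.36). The T cell receptor component Cd3d (0.54) was also higher. Of 24 embryo markers 2 were higher, Afp (0.42 ± 0.42, SD over 2 probes) and Krt5 (0.36), and Col2a1 was lower (-0.43). The genes ranked highest at 7 h included Pgs1 (1.81), Siglecf (1.93) and Xist (0.87), and the lowest Gas8 (-1.09), Trappc1 (-0.81) and Zbtb7a (-0.80), each on 1 probe. The probes of Pgs1 and Xist shared the order of signs of Ptger4. Irf7 differed by 0.06, Irf1 by 0.15, Ifit1 by 0.10, Atf3 by 0.10, Sod2 by 0.05, Il1rn by 0.05, Marco by 0.02, Nfkbia by -0.02, Jun by -0.01, Ccl5 by -0.06, Tlr2 by -0.11, Fos by -0.11, Ptgs2 by -0.16 and Saa3 by -0.22. All probes of a gene were past the size rule upwards in 8 genes and downwards in 0, within the upper limits of 9 and 2 for shuffled probes. Simulated arrays put 3.85% of unchanged genes past the size rule, where 4.74% were past it. The share of higher genes among those past the size rule was 70.6%, and 47.0% with the trend on the mean ratio removed (170 higher and 192 lower) and 52.5% after quantile normalization (310 and 280). With the 0.5 h array left out of the filter 194 genes were lower, and against that array Nfkbie (-0.28), Cd3d (-0.60), Arg1 (-0.15), Afp (-0.45) and Krt5 (-0.34) were lower.

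At 21 h, 366 genes were higher and 396 lower. Of 22 interferon-stimulated genes 6 were lower, among them Cxcl10 (-0.45, 1 probe), a chemokine induced by interferon, Psmb9 (-0.38 ± 0.16, SD over 2 probes) and Ifit1 (-0.32 ± 0.03, 2 probes), while Stat2 (0.31) and Ifi204 (0.32) were higher. Rsad2 (-0.38 ± 0.51) and Oasl2 (-0.36 ± 0.66) had a spread over their 2 probes wider than the difference, and the probe of highest ratio put Oasl2 at 0.11. The list median was 0.01, inside the range of random lists. Ptger4 was lower by -0.57 ± 0.07 (SD over 3 probes). Ly86, which encodes MD-1, was higher by 0.64, and the 7 LPS and TLR recognition genes had a median of 0.20, at percentile 99.7.

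Among other lists at 21 h, Plaur (-0.56) and Saa3 (-0.31) were lower and the median of the 15 inducible effectors was -0.09, at percentile 1.48. Fabp5, a fatty acid binding protein, was higher by 0.38 ± 0.04 (SD over 3 probes). The proliferation genes Mki67 (0.44) and E2f1 (0.45) were higher, 3 of 30 cell cycle genes in all, and Gins2 was lower (-0.30 ± 0.11, SD over 2 probes), with a list median of -0.02. Among 13 immediate early genes Fos was lower (-0.40) and Egr2 higher (0.35), and Birc3 (0.50) and Col1a2 (0.68) were higher. The genes ranked highest at 21 h included Adamts3 (1.16), Svep1 (0.92) and Cd55 (0.95), an inhibitor of complement. The lowest included Prss32 (-1.04), Mlph (-0.99) and Ubd (-0.79). Each of these genes had 1 probe. The Ubd probe has a number near those of Ptger4 and shares their order of signs. Tlr2 differed by 0.28, Irf7 by 0.26, Jun by 0.06, Il1rn by 0.04, Atf3 by 0.02, Irf1 by -0.03, Marco by -0.07, Ccl5 by -0.07, Ptgs2 by -0.10, Nfkbia by -0.14 and Sod2 by -0.23. Simulated arrays with this spread put 8.24% of 8252 unchanged genes past the size rule, where 9.02% were past it. All probes of a gene were past it upwards in 9 genes and downwards in 10, beside upper limits of 11 and 9 for shuffled probes. The 10 include Ptger4 and Rbm34, whose probes have neighbouring numbers, which the shuffles did not keep. Against the 0.5 h array Oasl2 (0.96), Ifit1 (0.11) and Rsad2 (0.05) were higher and Egr2 (-0.77), Ifi204 (-0.75), Fabp5 (-0.0398) and Birc3 (-0.0996) lower, while Saa3 and the median of the inducible effectors were both at 0.00902, and after quantile normalization 705 genes were higher than at 0 h.

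**Figure D3:**
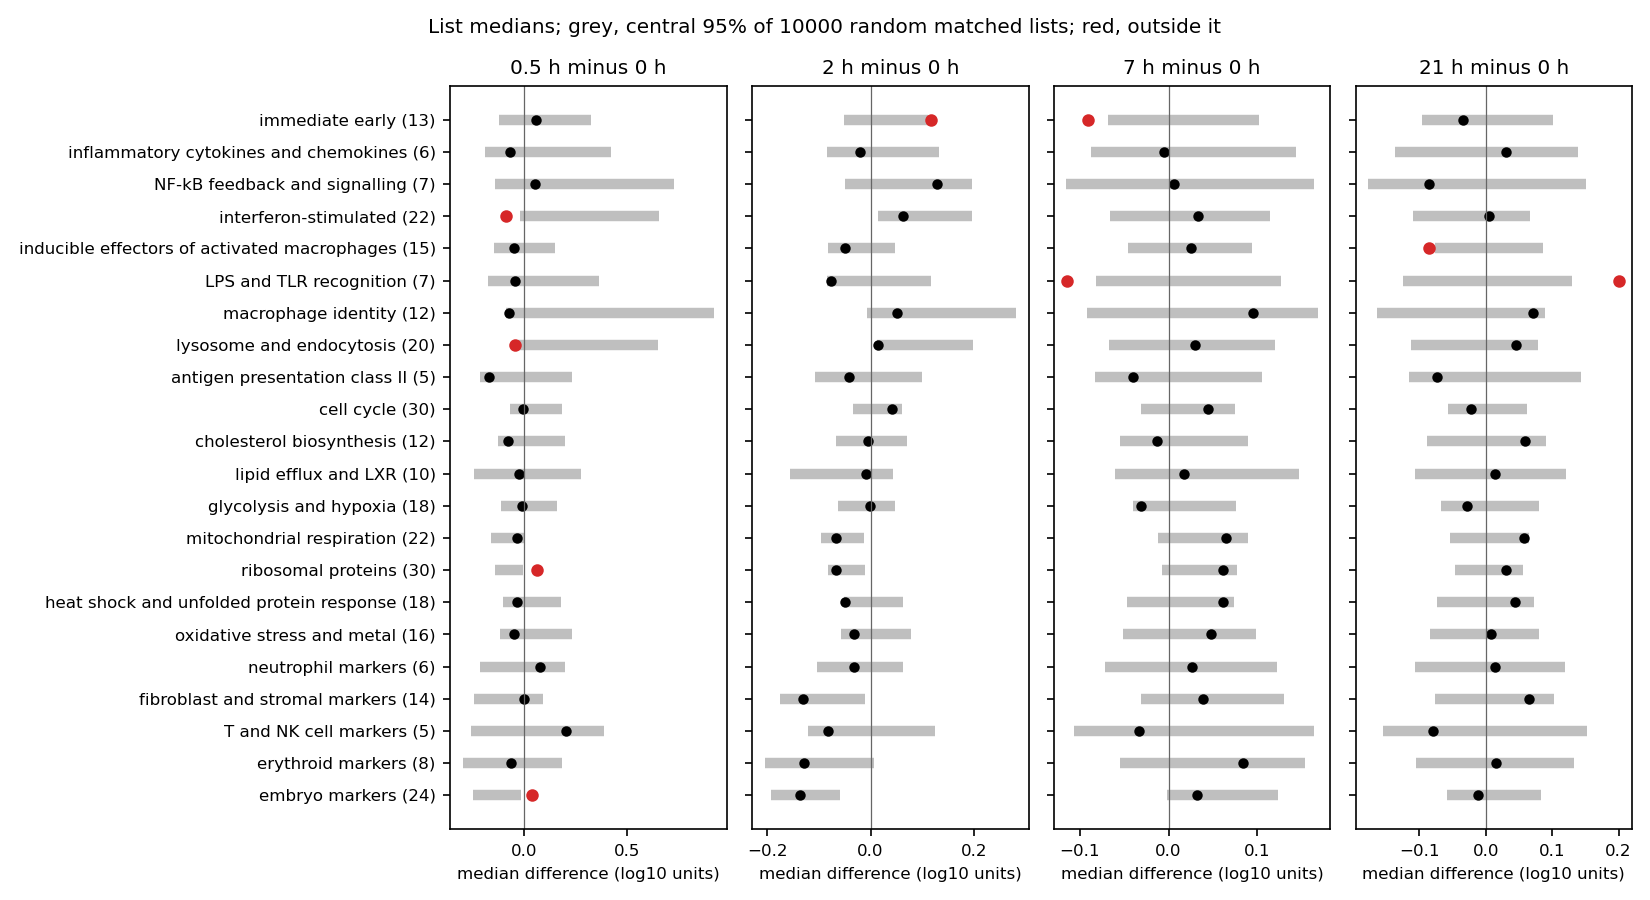
Median difference from 0 h (horizontal axis, log10 units) of each fixed list at 4 times, with the number of measured genes in brackets. Grey bars hold the central 95% of 10000 matched random lists, red points lie outside, and each panel has its own scale. Outside points number 4 at 0.5 h, 1 at 2 h, 2 at 7 h and 2 at 21 h, of 22 lists each.

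The remaining lists stayed inside the range of random lists at all 4 times. At 2, 7 and 21 h their medians were 0.05, 0.10 and 0.07 for macrophage identity, 0.13, 0.01 and -0.09 for NF-kB feedback, and -0.02, 0.00 and 0.03 for cytokines and chemokines. They were -0.04, -0.04 and -0.07 for class II antigen presentation, -0.01, -0.01 and 0.06 for cholesterol biosynthesis, and -0.01, 0.02 and 0.01 for lipid efflux. Glycolysis gave 0.00, -0.03 and -0.03, mitochondrial respiration -0.07, 0.06 and 0.06, heat shock -0.05, 0.06 and 0.04, and oxidative stress -0.03, 0.05 and 0.01. Among markers of other cells, neutrophil genes gave -0.03, 0.03 and 0.01, fibroblast genes -0.13, 0.04 and 0.06, and T and NK cell genes -0.08, -0.03 and -0.08. Across the 88 list medians 9 lay outside, where 4.4 would by construction.

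The time points shared the 0 h array, so their differences share its chance values. Across genes the correlation of the differences at 0.5 and 2 h was 0.32, beside 0.09 simulated for unchanged genes (covariance 0.026 and 0.0055). At 2 and 7 h it was 0.14, beside 0.25 simulated (covariance 0.0041 and 0.0056), and at 7 and 21 h 0.01, beside 0.21. At 2 and 21 h it was 0.18, beside 0.24, at 0.5 and 7 h -0.07, beside 0.08, and at 0.5 and 21 h 0.17, beside 0.08. The numbers of genes higher at both 2 and 7 h and lower at both were 78 and 27, where independent lists give 12.0 and 3.04. Both sets of differences contain the same 0 h values. In the 3 pairings that share no array the correlation was 0.04 (2 h from 0 h with 21 h from 7 h), -0.10 (7 h from 0 h with 21 h from 2 h) and -0.14 (21 h from 0 h with 7 h from 2 h).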

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

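The tests of the globin probes, of the agreement between probes at 0.5 h, of the single Ptger4 spot and of the stretches chosen on the 7 and 21 h arrays were chosen only after their results were seen; the other tests were set down before, except that the limit from probe noise and the repeat over reliable stretches in the last paragraph were added once the first value of that test was known. Ptger4 stood out because its difference from 0 h was 1.08 at 2 h and -0.57 at 21 h, with all 3 probes of opposite sign at these times; the contrast was not tested, since each time has 1 array. Probes without a single gene symbol, left out of the comparisons of genes, also carried differences: 61 were higher and 84 lower at both 2 and 7 h.

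For Ptger4, the lowest of the 3 probes was higher by 0.91 at 2 h. The pattern was already stated for all 3 probes, so a single faulty spot could not give it and that test adds no support. After the trend of the difference with the ratio was removed, 0.63 was left, past the bound set beforehand, with an SD over probes of 0.16. Ptger4 lies near the upper end of the ratios (0.69 at 0 h and 1.77 at 2 h), where few genes define the trend. The SD over probes is not the error of the trend, so a trend as the whole cause is not excluded. The place on the array is not excluded: among 361 other probes within the 400 numbers around these 3, 19 were also higher at 2 and 7 h and lower at 21 h, beside 82 of 17675 elsewhere, 11.3 times the share. Neighbours with that order of signs include Rbm34, Ubd and Retn. Probe number stands here for place, but the sources used do not say how numbers map to the array. An effect shared by probes of neighbouring numbers, from place or otherwise, may therefore account for the Ptger4 differences. A response of the receptor gene to LPS stays open and untested.

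The 0.5 h array had more genes past the size rule than any later one. Loss of embryo signal on part of that array is a candidate cause, since 28 globin probes that read below -1 elsewhere read above -0.5 there. Another 27 such probes stayed below -1, some of them among the same probe numbers, so loss over whole stretches is not shown. An early response to LPS is neither shown nor excluded: probes of a gene had a correlation of 0.0284 (bootstrap interval -0.02 to 0.07), but 0.17 after the trend was removed and 0.19 over the reliable stretches. The bound of 0.5 set for it lies far above these values and above the 0.14, 0.07 and 0.10 of the later arrays, so that test decides nothing. The trend was fitted on the mean of the arrays compared, so the 0.17 may partly hold the 0 h ratio itself.

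Differences at 0.5 and 2 h had a correlation across genes of 0.32. For a wider range of ratios, the 0.31 left after the trend was removed decides nothing. That trend is fitted on the mean of the arrays compared, and the simulated 0.09 was for differences without this step. Unreliable stretches of the 0.5 h array are argued against as the whole cause by 0.41 over 2730 genes. These genes lie in 10 stretches where that array follows the 7 and 21 h arrays, and the shared 0 h array alone gave 0.12. All 10 are also among the 15 stretches of the next value. A choice on correlation does not remove shifts of whole stretches. Some of the 15 moved the same way on both arrays: probes 4001 to 4400 had a deposited median of 0.02 at 0 h, 0.24 at 0.5 h and 0.07 at 2 h. Others did not, such as probes 6401 to 6800 with 0.03, -0.05 and 0.05. How much of the 0.41 a shift common to the 0.5 and 2 h arrays gives was not tested. The 0.43 over 15 stretches chosen with the 2 h array included decides nothing, since that choice favours it. For a response to LPS, the 0.5 h difference of 1 probe was set against the 2 h difference of another probe of the gene. Their correlation was 0.0164 (-0.0202 to 0.0496), with its upper end just under the bound of 0.05 set beforehand. Probe noise would hold it to 0.111 at most. That limit rests on the agreement of 0.17 at 0.5 h after the trend was removed, which may partly hold the 0 h ratio. Without that step probes of a gene had a correlation of 0.0284 at 0.5 h and 0.14 at 2 h. The limit may thus lie nearer the bound, and the test decides nothing about a shared response. Over reliable stretches the correlation was 0.0538 (-0.0401 to 0.144, 487 genes), which also leaves the response undecided. A property of single spots, such as weak signal, could give a shared difference within but not between probes; it was not tested, since no intensities were used.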

How the results depend on the processing

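The readings as base 2 or e, the reliable stretches, the left-out 0.5 h array, centring on probes, the running median and the left-out last stretches were chosen after the data were seen. Of the counts under other settings 78 stayed within 1.5 times the value reported and 62 did not; among list medians 821 moved by less than the SD of random lists, 180 moved by more and 5 changed sign. Of the values of named genes 1392 moved by less than the SE from the spread between probes, 296 by more and 42 changed sign, and under quantile normalization 3 of the 6 correlations between times moved by 0.1 or more: 0.5 with 7 h to 0.0516, 0.5 with 21 h to 0.31 and 2 with 21 h to 0.33. Without centring, with the median probe, with centring on probes and with the running median all 8 counts stayed within 1.5 times. The last stretches hold no probe with a single gene among those compared, so leaving them out removed nothing; 8 of the 78 counts come from that setting and say nothing about stability. Spot intensities were not used here, so what signal over background limits is unknown. The cause of each difference below was not tested, except where the rule itself or the number of probes or genes sets the count.

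With the loess trend removed, 886 genes were higher at 0.5 h, and 170 were higher and 192 lower at 7 h. After quantile normalization 280 were lower at 7 h and 705 higher at 21 h, and after scaling to one median absolute deviation 212 and 559. With the probe of highest ratio 440 were higher at 7 h. With values on the 2 arrays compared, 542 were higher at 2 h and 208 lower at 7 h, and with the 0.5 h array left out 539 and 194. Over reliable stretches, which hold fewer genes, 609 were higher and 317 lower at 0.5 h.

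Against the 0.5 h array, 823 genes were higher and 1695 lower at 2 h, 1247 and 1630 at 7 h, and 1016 and 1784 at 21 h. Against the mean of the 0 and 0.5 h arrays 876 were lower at 2 h, 558 higher and 975 lower at 7 h, and 1071 lower at 21 h. Counting every probe gave 3589 higher and 2280 lower at 0.5 h, 890 and 708 at 2 h, 819 and 497 at 7 h, and 1000 and 1353 at 21 h.

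A size rule of 1.5 on the log2 scale left 415 lower at 0.5 h, 155 higher and 79 lower at 2 h, 126 and 30 at 7 h, and 139 and 141 at 21 h. A rule of 0.5 gave 2082 lower at 0.5 h, 1024 higher and 957 lower at 2 h, 1181 and 670 at 7 h, and 1301 and 1190 at 21 h. Read as base 2 the counts were 384 higher and 50 lower at 0.5 h, 19 and 7 at 2 h, 12 and 5 at 7 h, and 3 and 8 at 21 h. Read as base e they were 705 and 159, 54 and 14, 44 and 9, and 37 and 33.

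Values past the size rule, or outside random lists, that changed sign were these. Against the 0.5 h array, the difference at 2 h was -0.80 for Irf7, -0.44 for Egr2, -0.75 for Ier2, -0.84 for Nfkbie, -0.0982 for Fcer1g, 0.22 for F3 and 0.0627 for Cd79b. Against the 0.5 h array, the difference at 7 h was -0.28 for Nfkbie, -0.15 for Arg1, -0.60 for Cd3d, -0.45 for Afp and -0.34 for Krt5. Against the 0.5 h array, the difference at 21 h was 0.00902 for the median of inducible effectors of activated macrophages, 0.11 for Ifit1, -0.75 for Ifi204, 0.0522 for Rsad2, 0.96 for Oasl2, 0.00902 for Saa3, -0.0398 for Fabp5, -0.77 for Egr2 and -0.0996 for Birc3. Against the mean of the 0 and 0.5 h arrays, the difference at 2 h was -0.0371 for Irf7, -0.0834 for Ier2 and -0.14 for Nfkbie. Against the mean of the 0 and 0.5 h arrays, the difference at 7 h was -0.0274 for Cd3d and -0.0143 for Afp. Against the mean of the 0 and 0.5 h arrays, the difference at 21 h was -0.22 for Ifi204, 0.30 for Oasl2 and -0.21 for Egr2. With the loess trend removed, the difference at 0.5 h was -0.23 for Egr2, -0.36 for Fos, -0.94 for Irf7, -1.31 for Ccl9, -0.15 for Nfkbie and -1.10 for Plaur. With the loess trend removed, the difference at 2 h was -0.0305 for Fcgr1. With the median probe, the difference at 0.5 h was -0.000415 for the median of ribosomal proteins. With the probe of highest ratio, the difference at 21 h was 0.11 for Oasl2. After quantile normalization, the difference at 0.5 h was -0.0264 for Fos and -0.0318 for Plaur. After quantile normalization, the difference at 2 h was -0.21 for Fcgr1. After quantile normalization, the difference at 7 h was -0.0486 for Fcgr1. Over reliable stretches, the difference at 0.5 h was 0.25 for the median of interferon-stimulated, -0.0544 for the median of ribosomal proteins, -0.11 for the median of embryo markers and -0.43 for Hbb-b1. After scaling to one median absolute deviation, the difference at 0.5 h was 0.19 for Col1a1.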

Other observations

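Against whole embryo, 286 genes were at least 2-fold higher in macrophages on each of the 0, 2, 7 and 21 h arrays and 402 at least 2-fold lower. These genes were chosen after the data were seen. Ranked by the mean alone, whether or not each array passed, the 25 highest included Ifi204 at 1.20 ± 0.22 (SD over these 4 arrays), Tgtp1 at 1.25 ± 0.42, H2-Q8 at 1.24 ± 0.18 and B2m, the light chain of class I molecules, at 0.98 ± 0.11, and also Msln at 1.22 ± 0.85 and Pigh at 1.12 ± 1.05, which were below 2-fold at 21 h; no enrichment was tested. The 25 lowest included Myl1 (-1.58 ± 0.11), a myosin light chain of muscle, Krt1 (-1.38 ± 0.10), a keratin of skin, Postn (-1.45 ± 0.15) and Fga (-1.41 ± 0.22).

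In 12 genes the difference from 0 h was past the size rule in 1 direction at all 4 times, 3 higher and 9 lower. All 4 differences subtract the same 0 h value, so a single odd spot there could give this, which was not tested. On their 1 probe, Slc3a1 read 1.23 at 0 h and between -0.60 and -0.38 on the other arrays, and Vezf1 1.04 and between -0.69 and -0.46. Xist, on 1 probe, differed by -0.68, 0.81, 0.87 and -0.33 at 0.5, 2, 7 and 21 h. When the 0.5 h array was left out, 387 genes came in that had no value there. Of them 169 were higher and 13 lower at 2 h, and 8 higher and 82 lower at 7 h. Among the other 8452 genes 370 were higher and 218 lower at 2 h, and 307 and 112 at 7 h. The genes that came in thus stood apart on the 2 and 7 h arrays as well. Of 1104 probes without a value at 0.5 h, 112 had numbers from 4801 to 5200 and 90 from 5201 to 5600, the most of any stretches. The deposited median of the latter was 0.08 at 0 h and 0.24 at 2 h. Whether the genes that came in lie there was not checked, and the cause of their differences was not tested. The highest of them at 2 h included Prl7b1 (2.73), a prolactin family hormone of placenta, Spam1 (1.54), a sperm hyaluronidase, and Ropn1 (1.26).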
